A study of Chlamydomonas reinhardtii with 42 samples.

How the data were processed

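Transcripts of Chlamydomonas reinhardtii, a unicellular green alga, were measured by RNA sequencing in the strains A31 and DHC16 before and after cobalamin and thiamine were given to the cultures, and in A31 given rapamycin, an inhibitor of the TOR kinase. Per the labels, the vitamins deplete ClpP1, a subunit of the chloroplast Clp protease. The labels do not say which strain is depleted, and they do not say whether replicates are separate cultures, so p-values measure the spread between these libraries, which may be technical. The series text names 0, 12, 31, 43 and 48 h for the vitamins and 0, 2 and 8 h for rapamycin. The sample records cover 0, 12 and 48 h for the vitamins, and the times 31 and 43 h were not analysed here.

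The authors deposited a table of normalized counts, a signal per gene and library that equals the number of reads divided by 1 factor per library. This table holds 17 libraries and 17114 genes, and the table deposited for the rapamycin records holds the same values, so it was used a single time. All groups have 3 libraries except A31 at 48 h, which has 2, numbered 19 and 22. Its library 25 and the rapamycin libraries were not analysed here. The series has 42 records, 18 of the vitamin part and 24 of the rapamycin part, and 18 of the latter repeat the strain, time and number of a vitamin record. For rapamycin, the authors deposited mean transcript levels at 0, 2 and 8 h as a signal whose scale is not stated and differs from that of the count table. Beside these levels stand the authors' log2 fold changes (rapamycin over 0 h), p-values and adjusted p-values, per the file headers. The fold changes are headed as moderate, and they were read as moderated log2 values. At 8 h 339 of 1681 differed by more than 1 from the log2 ratio of the levels, with 0 differing in sign. Rankings here use the moderated values. The deposited p-values come with no statement of the test or the adjustment.

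Per the submitters' processing notes, CASAVA 1.8.2, TopHat 1.3.1, HTSeq 0.5.3p9 and edgeR 3.0.8 were used by the authors, without roles or settings. The genome build, the annotation, the strand setting and the normalization method are not given in the sources used here. Reads shared between close paralogs, such as HSP22E and HSP22F or the LHCBM genes, could have been split or dropped in counting, and the values of such genes are uncertain to that extent.

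In each library every value was a whole multiple of the value of 1 read within a tolerance of 0.01 (100% of values), and 1 read was worth 0.703 to 2.04 normalized counts. Whole reads were recovered from these steps, 7458423 to 13699705 per library. The deposited totals ran from 6350337 to 16502090. The 3 DHC16 libraries at 0 h had the highest deposited totals (11875128 to 16502090) and also the highest shares in their 10 most abundant genes (14.6 to 18.1%, against 5.7 to 14% elsewhere). A floor of 3 reads was used per library, and it covers counting error only.

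Genes with a mean of at least 1 (per-million scale) over the 17 libraries were tested, 14422 in all. The test was limma-trend on log2(normalized count + 1), with 1 mean per strain and time, all 17 libraries sharing the spread, and Benjamini-Hochberg adjustment over the tested genes at 0.05. Fold changes are on that log2 scale, which understates changes of low genes. The comparisons were 12 h and 48 h against 0 h in each strain, the difference between the strains of each of these changes, and the strains at 0 h. A strain difference of a change is given as the DHC16 change minus the A31 change, which is the same test as the one planned with the opposite sign. Because the unit is a normalized count, the count models edgeR quasi-likelihood and DESeq2 served as alternatives on the recovered reads. The planned limma fits of the rapamycin comparisons were not run, since no rapamycin library was at hand. For rapamycin, the authors' deposited values are given instead, with no test per gene of their own. The only test made on them was Fisher's test of gene groups chosen after the result was seen.

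Gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the alternative settings. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry beside it, in families of 10 lists per contrast. The background was the 766 tested genes that carry a name. Gene names come only from the authors' rapamycin tables, which name 780 genes, so each named gene and each list member had passed the authors' thresholds there. This makes the lists no independent evidence about rapamycin, and genes without a name are missing from every list. The mitochondrial ribosomal protein and 26S proteasome lists had 0 named members. The reference gene table holds 17742 genes and gave 0 symbols other than locus tags, although 12646 identifiers matched. No genome sequence was used, so no coordinates are given. The count table holds nuclear loci, and clpP1 itself, a chloroplast gene, was not analysed here, nor was a gene named NAC2.

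Named genes were chosen by a rule with 3 parts. The first takes the 10 largest rises and falls of the 48 h strain difference among named genes with adjusted p under 0.05, a log2 change of at least 1, a mean of at least 10 (per-million scale) and every A31 library at 48 h beyond every A31 library at 0 h. The rule took A31 as the depleted strain. It was also applied with DHC16 in its place, as an addition made after the data were seen. The other parts take a fixed set of marker genes, and of each list up to 2 genes that rose and up to 2 that fell with the smallest adjusted p. For rapamycin at 8 h, the 10 largest named rises and falls in the authors' table were taken, since the criteria per library could not be applied.

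The alternatives were other pseudocounts and filters, quantile and TMM-like scaling, robust eBayes, edgeR, DESeq2, only the groups compared, the replicate number as a block, and each library left out in turn. Scaling to the column total (per-million), all tested genes as list background, and list tests at 12 h were added after the data were seen. The methods were tested on simulated data with 14422 genes, of which 200 were changed. Of changes of 2, 4 and 8-fold, limma recovered 44, 99 and 100% for the DHC16 change at 48 h and 2, 81 and 98% for the strain difference of that change. The simulation gave all genes the same dispersion, changed few genes and held no discordant A31 48 h libraries. These shares therefore do not give the power of the real comparisons. In the simulated contrast without changes, DHC16 at 12 h, limma and edgeR each made 0 calls. At 2, 4 and 8-fold, limma called 10, 15 and 9 unchanged genes for DHC16 at 48 h and 1, 9 and 7 for the strain difference. With edgeR these were 4, 5 and 5, and 1, 11 and 7. The work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.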

Results

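RNA was sequenced in the Chlamydomonas strains A31 and DHC16 at 0, 12 and 48 h after cobalamin and thiamine were given to the cultures, with 3 libraries in each group except A31 at 48 h, which had 2. The vitamins were given to deplete ClpP1, a subunit of the chloroplast Clp protease, and no culture without vitamins was available at 12 or 48 h. Changes with time therefore hold any effect of growth or of the time of sampling as well. The libraries held 7458423 to 13699705 reads. The first principal component of the log2 values took 56.9% of the variance and parted the 0 h from the 12 h libraries, and the second took 20.8% and set DHC16 at 48 h apart. The A31 libraries at 48 h lay far from each other. Library 19 had a mean rank correlation of 0.943 with the A31 0 h libraries and 0.813 with those of 12 h, whereas library 22 had 0.775 and 0.919. The rank correlation between libraries 19 and 22 was 0.854, while the lowest pair within A31 at 0 h had 0.979.

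**Figure D1:**
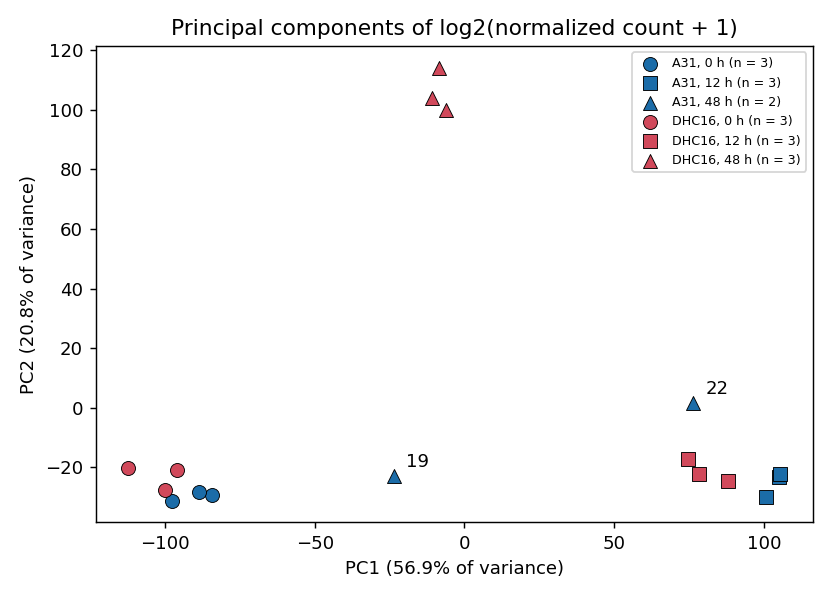
Principal components of log2(normalized count + 1) for the 17 libraries, with the share of variance on each axis (56.9% and 20.8%) and 1 point per library, coloured by strain and shaped by time. Library 19 of A31 at 48 h sits nearer the 0 h libraries and library 22 nearer the 12 h libraries, and DHC16 at 48 h sits apart from all others.

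METE, the cobalamin-independent methionine synthase whose transcript is known to be repressed by cobalamin, served as the marker of the vitamins, since the targeted clpP1 was not analysed here. METE (Cre03.g180750) fell in A31 from 814 ± 235 normalized counts at 0 h to 150 ± 13.1 at 12 h (SD, n = 3 each), a log2 change of -2.39 ± 0.30 (SE, adjusted p = 5.9e-06). In DHC16 it fell from 841 ± 225 to 264 ± 4.54 at 12 h (log2 -1.63 ± 0.30, adjusted p = 0.00021) and stood at 323 ± 28.8 at 48 h (log2 -1.35 ± 0.30, adjusted p = 0.0012). With per-million scaling the DHC16 fall was smaller at 12 h (log2 -0.88) and at 48 h (-0.3), and that at 48 h was not called. In A31 at 48 h the libraries differed, with 1001 normalized counts in library 19 and 353 in library 22. The first lay within the A31 0 h values of 579 to 1050. The A31 change at 48 h had a log2 of -0.41 ± 0.33 (n = 2 against 3, adjusted p = 0.38), and the difference between the strains was not called (log2 -0.93 ± 0.45, adjusted p = 0.17), although it was called without library 22 (log2 -1.68).

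**Figure D2:**
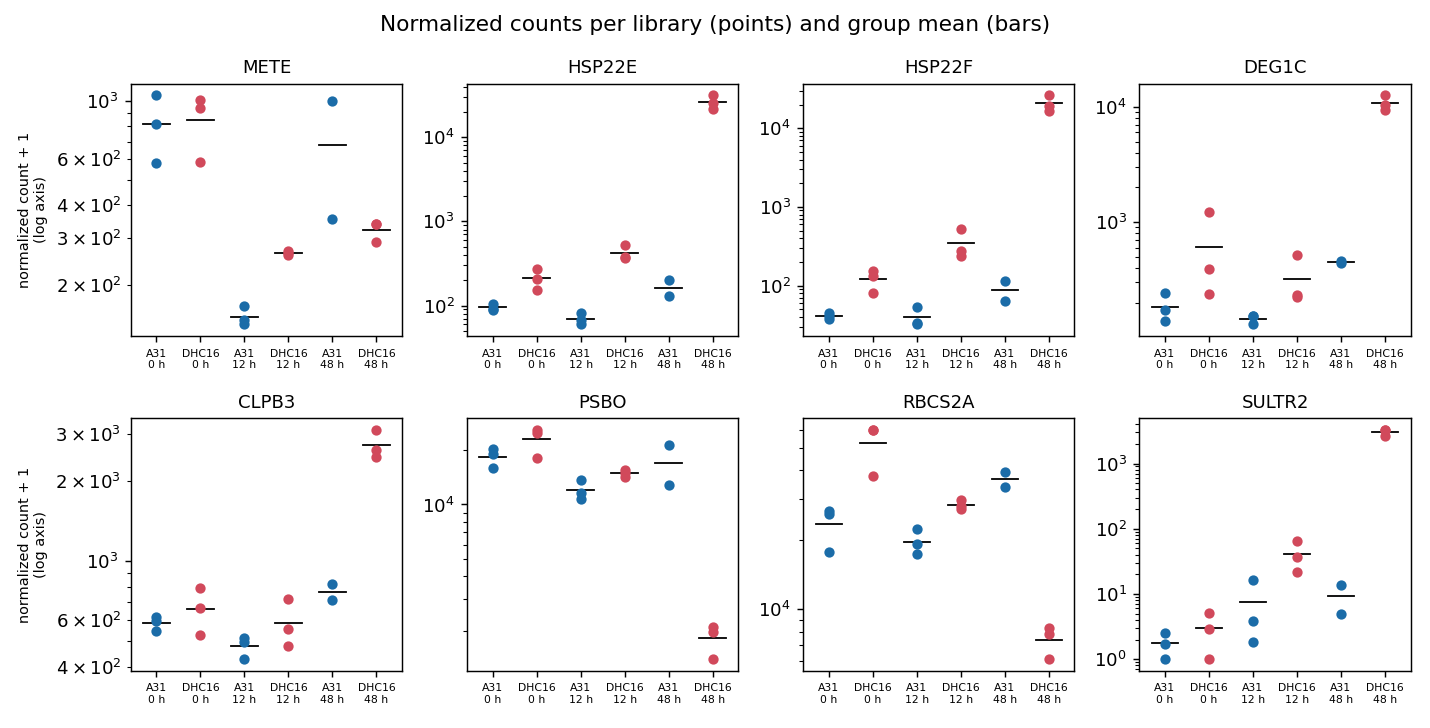
Normalized counts (+ 1, log axis) of 8 genes in each library, with points for libraries and bars for group means by strain and time. HSP22E, HSP22F, DEG1C, CLPB3 and SULTR2 stand highest and PSBO and RBCS2A lowest in DHC16 at 48 h, and the METE points of A31 at 48 h lie far apart (1001 and 353).

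At 12 h genes of DNA replication and the cell cycle rose in both strains. All 33 measured members rose in A31, with a median log2 change of 3.53, and 32 rose in DHC16, with a median of 3.01. CYCA1, an A-type cyclin, went from 11 ± 3.85 to 1693 ± 156 normalized counts in A31 and from 16.7 ± 2.78 to 1180 ± 187 in DHC16 (SD, n = 3), log2 changes of 7.18 ± 0.32 and 6.06 ± 0.32 (adjusted p = 3.7e-11 and 5.4e-10). RPA30, a subunit of the single-strand binding protein of replication, rose by log2 2.79 ± 0.21 in A31 and 2.92 ± 0.21 in DHC16. FAP212, a flagella associated protein, rose from 9.07 ± 4.08 to 9649 ± 2248 normalized counts in A31 and from 36.6 ± 10.4 to 6891 ± 2559 in DHC16. The autophagy genes APG8 and APG3 fell in both strains, APG8 by log2 -1.14 ± 0.25 in A31 and -1.32 ± 0.25 in DHC16.

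Nuclear genes of plastid ribosomal proteins fell at 12 h, 20 of 28 in A31 and 25 of 28 in DHC16, with medians of -0.71 and -0.94 (-0.38 and -0.19 with per-million scaling). PRPL13 fell by log2 -1.51 ± 0.20 in A31 and -2.07 ± 0.20 in DHC16 (adjusted p = 8.9e-06 and 3.6e-07). Of 21 genes of the photosystems, light harvesting and the Calvin cycle, 14 rose and 3 fell in A31, and 13 rose and 4 fell in DHC16. LHCB5, a minor light-harvesting protein, rose by log2 2.07 ± 0.56 in A31 and 1.79 ± 0.56 in DHC16, and PSBO, of the oxygen-evolving complex, fell by log2 -0.62 ± 0.22 and -0.61 ± 0.22. The PSBO falls were not called with quantile or per-million scaling, and in DHC16 the second gave a rise (log2 0.15). HSP70B, the chloroplast Hsp70 chaperone, rose from 547 ± 127 to 2474 ± 201 normalized counts in A31 (log2 2.2 ± 0.49, adjusted p = 0.0011) and by log2 1.66 ± 0.49 in DHC16. The small heat shock protein genes HSP22E and HSP22F rose in DHC16 at 12 h (log2 1.04 ± 0.23 and 1.47 ± 0.32), and their A31 values were -0.47 ± 0.23 and -0.08 ± 0.32 (adjusted p = 0.088 and 0.84). In the test of the strain difference of the 12 h change neither was called, nor was any of the 8 chloroplast chaperones. With adjustment over that list alone 2 of the 8 rose more in DHC16.

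Over all 14422 genes, limma called 8634 in A31 at 12 h (4537 rose, 4097 fell) and 8153 in DHC16 (4340 rose, 3813 fell). Of the genes that rose, 3632 did so in both strains, where independent lists would share 1365, and 2952 fell in both against 1083. The log2 changes correlated across genes with r = 0.928, a description only, since genes are not independent replicates. With per-million scaling, 69.6% of the calls rose in A31 and 86.2% in DHC16, and the medians of all genes shifted to log2 0.35 and 0.78. With camera the replication list (adjusted p = 5.2e-12 in A31 and 4.6e-09 in DHC16) and the plastid ribosomal list (adjusted p = 2.5e-06 and 2.7e-12) passed in both strains. With an estimated correlation none of these passed (adjusted p = 0.51 and 0.46 for replication, 0.85 and 0.46 for plastid ribosomal proteins).

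The 12 h changes differed between the strains at 36 genes, 22 with a higher and 14 with a lower change in DHC16. With the replicate number as a block 11 genes were called, 9 of them among the 36. Of the 36, the named ones included FAP212, which rose less in DHC16 (difference -2.47 ± 0.43, adjusted p = 0.033), and ACS3, an acetyl-CoA synthetase, with 16496 ± 209 normalized counts at 0 h and 25678 ± 2111 at 12 h in A31 against 7100 ± 126 and 26236 ± 2596 in DHC16 (difference 1.25 ± 0.25, adjusted p = 0.047). FAP289, a flagellar protein, fell in A31 (log2 -1.32 ± 0.23) and had 0.31 ± 0.23 in DHC16 (difference 1.63 ± 0.32, adjusted p = 0.043). Its levels were 339 normalized counts at 0 h and 137 at 12 h in A31 against 162 and 200 in DHC16. No member of the replication or plastid ribosomal lists was called, although camera placed both lower in DHC16 (medians -0.51 and -0.23, adjusted p = 0.00034 and 0.0019, and 0.86 for both with an estimated correlation). The count of 36 moved to 3 without DHC16 library 16 of 12 h, to between 5 and 21 without 10 of the other 11 libraries of 0 h and 12 h, to 426 without either A31 48 h library, through the shared spread, to 183 with DESeq2 and to 335 with per-million scaling.

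At 48 h the chaperone and protease genes of the chloroplast rose in DHC16. HSP22E, a small heat shock protein of the chloroplast (Cre14.g617450), went from 209 ± 60.6 to 26164 ± 5190 normalized counts (SD, n = 3 each, log2 6.98 ± 0.23, adjusted p = 2.3e-12). HSP22F went from 121 ± 37.9 to 20669 ± 5146 (log2 7.43 ± 0.32, adjusted p = 6.1e-11), CLPB3, a ClpB unfoldase, from 659 ± 133 to 2716 ± 341 (log2 2.05 ± 0.18) and the protease DEG1C from 612 ± 524 to 10758 ± 1703 (log2 4.47 ± 0.43). VIPP1, a protein of thylakoid membrane upkeep, rose by log2 1.57 ± 0.29, whereas CGE1a, the exchange factor of the chloroplast Hsp70, stood at 2110 ± 996 and 1978 ± 143 (adjusted p = 0.99). Of the 8 chaperones 6 rose, and all 5 proteases did. Both autophagy genes rose, APG8 from 1655 ± 425 to 8857 ± 1166 normalized counts (log2 2.44 ± 0.25, adjusted p = 6.1e-07).

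Transcripts of photosynthesis fell in DHC16 at 48 h, 12 of 21 with none rising, and the median of -1.24 was -0.20 with per-million scaling. PSBO fell from 22917 ± 4268 to 1819 ± 376 normalized counts (SD, n = 3, log2 -3.66 ± 0.22, adjusted p = 2.4e-09), and RBCS2A, the small subunit of Rubisco, from 52492 ± 12616 to 7401 ± 1165 (log2 -2.81 ± 0.23). NAB1, an RNA binding protein that is known to repress translation of light-harvesting transcripts, fell from 3608 ± 477 to 103 ± 40.0, and RBD2, a rubredoxin, from 2343 ± 493 to 78.7 ± 31.8. Plastid ribosomal protein genes fell at 26 of 28, with a median of -1.0 that became 0.05 with per-million scaling. The sulfate transport genes SLT2 and SULTR2 were among the largest rises. SLT2 went from 106 ± 18.3 to 4978 ± 485 (log2 5.55 ± 0.15) and SULTR2 from 2.00 ± 2.04, under the floor of 3 reads, to 3061 ± 343. SLT3 rose less (log2 1.64), whereas SULTR3 had -0.31, and no list of sulfate genes was fixed beforehand. Replication genes were above their 0 h level at 25 of 33, with a median of 1.87, and of the oxidative stress genes 8 of 11 rose and 1 fell, among them FSD1, an iron superoxide dismutase (log2 2.95 ± 0.33).

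In DHC16 at 48 h, 7933 genes were called (4290 rose, 3643 fell), and with per-million scaling 92.4% of the calls rose, with the median of all genes at log2 1.07. Camera placed 6 of 10 lists apart, namely chaperones (adjusted p = 0.0037), proteases (0.032), photosynthesis (0.00023), plastid ribosomal proteins (3.6e-08), replication (9.9e-05) and oxidative stress (0.032). None passed with an estimated correlation (adjusted p = 0.37 for each of the 6). The remaining lists were not called by camera. They included cytosolic, ER and mitochondrial chaperones (4 of 5 rose, adjusted p = 0.14), chlorophyll synthesis (4 rose and 1 fell of 8, 0.46), nitrogen assimilation (2 rose and 2 fell of 6, 0.63) and storage metabolism (4 rose and 5 fell of 10, 0.32).

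In A31 at 48 h replication and cell cycle genes stood above 0 h, 27 of 33 with none below and a median log2 of 1.75. CYCA1 had 176 normalized counts in library 19 and 548 in library 22, both above the 7.73 to 15.3 of the 0 h libraries, and FAP212 had 2182 and 3028 against 5.34 to 13.4. The chloroplast stress genes stayed far below their DHC16 levels, with HSP22E at 163 ± 49.4 and HSP22F at 87.4 ± 36.0 normalized counts (SD, n = 2). Their changes passed the test with both libraries (log2 0.75 ± 0.26 and 1.04 ± 0.36, adjusted p = 0.040 for each) but not without library 22 (adjusted p = 0.44 for each). HSP70B (log2 1.41 ± 0.55, adjusted p = 0.065) stood at 496 in library 19, within the 0 h range of 406 to 653, and at 4104 in library 22. Of the 21 photosynthesis genes 9 rose and none fell with both libraries in the fit, and none of the 28 plastid ribosomal genes was called. Named photosynthesis genes differed between the libraries. In library 19 LHCB5 (1194) and PSBX (5900) lay within their 0 h ranges, and PSBP1 (8458) and PSBO (12748) lay below theirs. In library 22 they stood at 10545, 15978, 21174 and 21375, above all A31 0 h libraries. RBCS2A stood above its 0 h range in both (39458 and 33808).

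The A31 comparison at 48 h called 3892 genes (2071 rose, 1821 fell). The count was 953 without library 22 and 7205 without library 19, 2568 and 2589 without A31 library 1 or 7 of 0 h, and 297 with only the A31 groups in the fit. With edgeR 64.2% of the calls rose, and with per-million scaling 29%. Of the lists camera called the replication list (adjusted p = 1.1e-08, and 0.81 with an estimated correlation), and the photosynthesis list had adjusted p = 0.092. Of the genes that rose, 1345 did so in DHC16 as well, where independent lists would share 616, and 1242 fell in both against 460 (r = 0.579 across genes).

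The 48 h changes of the strains, the main comparison of the vitamin part, differed at genes such as SULTR2, HSP22F, RBD2 and PSBX. SULTR2 had a difference of 7.94 (adjusted p = 7.7e-05), whose size depends on the pseudocount, since its DHC16 level at 0 h lay under the floor. HSP22F and HSP22E rose more in DHC16, by log2 6.39 ± 0.48 and 6.23 ± 0.34 (adjusted p = 3.2e-07 and 1.1e-08). DEG1C rose more by 3.14 ± 0.64, APG8 by 2.62 ± 0.37, APG3 by 1.69 ± 0.37 and CLPB3 by 1.67 ± 0.27. SLT2, a sodium and sulfate co-transporter, rose more by 5.28 ± 0.23, and BCS1, an assembly factor of the respiratory chain, by 4.35 ± 0.88, with 109 normalized counts in library 19, 1239 in library 22 and 9063 ± 1304 in DHC16 (n = 3). RBD2 (-5.42 ± 0.36, adjusted p = 8.5e-08), NAB1 (-4.34 ± 0.36), PSBX, a small photosystem II subunit (-4.26 ± 0.43), PSBO (-3.51 ± 0.33) and RBCS2A (-3.47 ± 0.34) went lower in DHC16.

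Other genes moved in opposite directions. RDP3, a rhodanese domain phosphatase, went from 60.5 ± 4.06 to 12.7 ± 14.1 normalized counts in A31 and from 176 ± 43.8 to 1169 ± 83.7 in DHC16 (difference 5.45 ± 0.71, adjusted p = 5.8e-05). AOT4, an amino acid transporter, went from 49.5 ± 6.37 to 19.3 ± 18.2 and from 142 ± 62.7 to 1213 ± 229 (difference 4.84 ± 0.69), although its A31 fall was not called without library 22 (adjusted p = 0.53). ACS3 and MAS1, malate synthase, of acetate use, went lower in DHC16 (differences -2.07 ± 0.26 and -1.59 ± 0.23). The MAS1 difference was not called with quantile or per-million scaling. FAP212 and GAS28, a cell wall glycoprotein, rose in both strains but less in DHC16 (differences -4.69 ± 0.46 and -4.74 ± 0.45). The calls of HSP70B (2.39 ± 0.73) and VIPP1 (1.35 ± 0.43) each ended in 7 of the leave-outs, HSP70B at log2 0.86 (adjusted p = 0.12) without library 19, and also with edgeR (adjusted p = 0.11) and DESeq2 (0.075).

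By list, 5 of 8 chloroplast chaperones rose more in DHC16 and none less (median 1.58, or 2.85 with per-million scaling, adjusted over the list alone also 5). Of the proteases 3 of 5 rose more (median 0.97, or 2.24 with per-million scaling, list alone 4). Of the photosynthesis genes 15 of 21 went lower (median -2.59, or -1.32 with per-million and -1.93 with quantile scaling, adjusted over the list alone 19), such as LHCB4 (-2.99 ± 0.50) and PSBQ (-3.03 ± 0.34). The changes themselves had medians of -1.24 in DHC16 and 1.17 in A31, where libraries 19 and 22 differed. Plastid ribosomal proteins went lower at 22 of 28 (median -1.0, adjusted over the list alone 26), a direction that turned with per-million scaling (median 0.26) and whose median was -0.34 with quantile scaling. Both autophagy genes rose more, and the 3 cytosolic ribosomal protein genes went lower (median -2.60), with RPL37a and RPS25 not called with quantile scaling. The replication genes went apart, 2 higher and 6 lower of 33, with MCM5, a helicase subunit, at 1.85 ± 0.27 and CYCA1 at -2.76 ± 0.48. Oxidative stress genes rose more at 3 of 11, nitrogen genes went lower at 2 of 6 and storage genes at 3 of 10. Chlorophyll genes had CHLM higher (1.48 ± 0.38) and DVR1 lower (-0.91 ± 0.28) of 8, and of the stress-induced light-harvesting relatives OHP1 was lower (-0.80 ± 0.24). The DVR1 and OHP1 differences changed sign with per-million scaling. No cytosolic, ER or mitochondrial chaperone was called of 5, and the vitamin marker METE was not called.

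In all 2584 genes differed, 1335 with a higher and 1249 with a lower change in DHC16. Camera called the chaperone (adjusted p = 0.00053), protease (0.031), photosynthesis (1.2e-09) and plastid ribosomal lists (8.2e-09), and with an estimated correlation each had an adjusted p = 0.29. For the other lists it gave adjusted p = 0.20 for replication, 0.14 for oxidative stress, 0.21 for nitrogen, 0.20 for storage, 0.68 for chlorophyll synthesis and 0.21 for the non-plastid chaperones. The count was 4188 without A31 library 22, 3790 without library 19, 1671 with only the 4 groups in the fit and 9587 with per-million scaling, where 95.5% of the calls were higher and the median of all genes was log2 1.28.

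**Figure D3:**
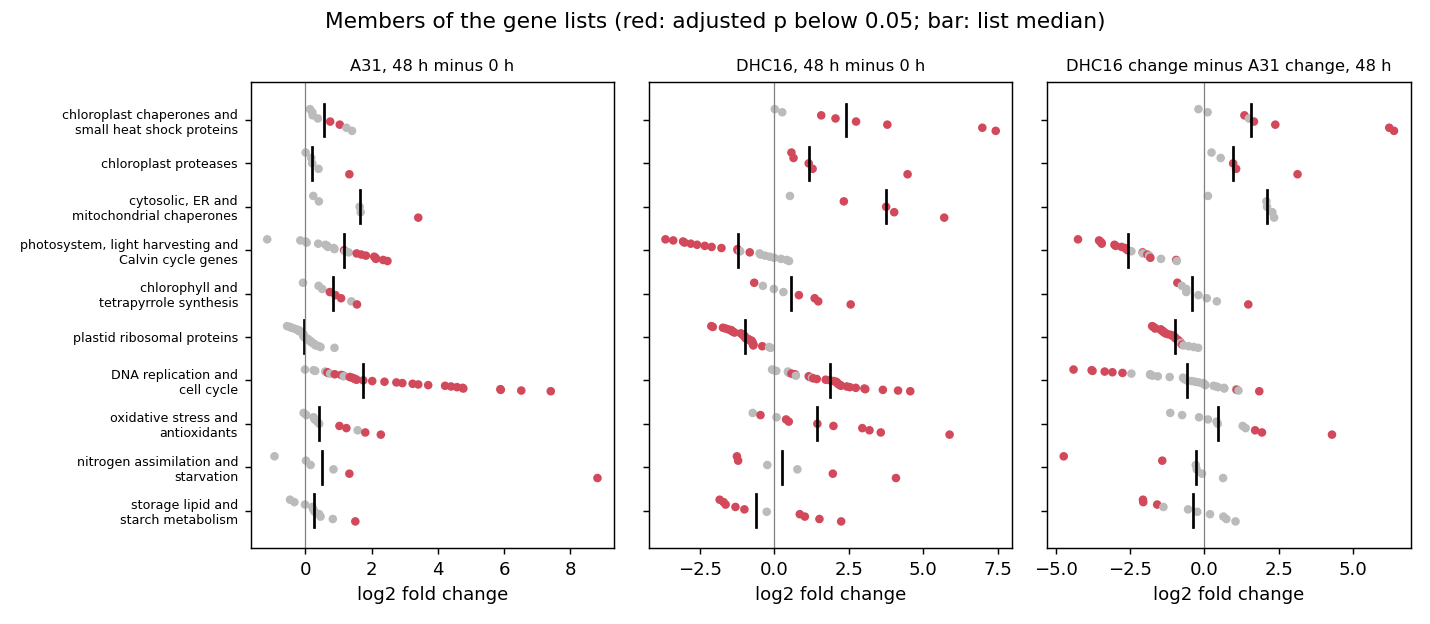
Log2 fold changes of the members of 10 gene lists at 48 h in A31, in DHC16, and as the DHC16 change minus the A31 change, with 1 point per gene, red where adjusted p was under 0.05, and a bar at the list median. In the strain difference the photosynthesis median is -2.59 (-1.32 with per-million scaling) and the chaperone median 1.58 (2.85 with that scaling). The plastid ribosomal median of -1.0 turns to 0.26 with per-million scaling.

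The strains differed before the vitamins were given. PTB2, a sodium and phosphate symporter, had 382 ± 47.3 normalized counts in DHC16 and 46.1 ± 15.9 in A31 at 0 h (SD, n = 3 each, log2 3.07 ± 0.33, adjusted p = 3.6e-05). RPL37a and RPS25 of the cytosolic ribosome were higher in DHC16 (log2 1.70 ± 0.31 and 1.59 ± 0.30), which was not called with quantile scaling (adjusted p = 0.059 and 0.14). ACS3 (log2 -1.22 ± 0.18, adjusted p = 0.00056) and MCM5 (-0.79 ± 0.18) were lower in DHC16. HSP22E and HSP22F were higher (1.1 ± 0.23 and 1.52 ± 0.32), though not called with per-million scaling (adjusted p = 0.20 and 0.062). METE stood at a log2 difference of 0.05 ± 0.30 (adjusted p = 0.94).

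At 0 h 1353 genes differed, 681 higher and 672 lower in DHC16. The count was 7444 with per-million scaling, with 1.6% of the calls higher and the median of all genes at log2 -0.71, and 769 with quantile scaling. Leave-outs gave 535 without A31 library 7, 779 without A31 library 1, 898 without A31 library 4, 885 without DHC16 library 1 and 737 without DHC16 library 4, and 2568 and 2567 without A31 48 h library 19 or 22, through the shared spread.

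Rapamycin in A31 was studied to inhibit TOR, a kinase that promotes growth. In the authors' deposited table at 8 h, the largest named rises were PHC24, a cell wall pherophorin (log2 6.39, adjusted p = 3.5e-129), HSP22F (5.06, adjusted p = 2.9e-07), DEG1C (4.73), HSP22E (4.46), THB1, a truncated hemoglobin (4.21), BCS1 (4.08), NRX2, a nucleoredoxin (3.89), AIH2, agmatine iminohydrolase (3.70), HLA8 (3.58) and FAP211 (3.57). The largest named falls in the authors' deposited table were FMG1-2, a flagellar membrane glycoprotein (log2 -5.88, adjusted p = 4.9e-17), PHC22 (-4.48), FAP12 (-4.27), FAP212 (-3.99), FAP170 (-3.58), PHC4 (-3.25), FAP35 (-3.14), MST1 (-3.14), SFI1 (-3.01) and GOX18 (-2.92). VIPP1 was raised at both times in the authors' deposited table (log2 2.32 at 2 h and 2.26 at 8 h), as was APG8 (1.5 and 1.73), and METE was raised at 8 h (1.99). LHCSR1, a stress-related light-harvesting protein, was raised at 2 h (log2 4.13), whereas in the vitamin libraries it lay under the floor of 3 reads throughout.

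By list, the authors' deposited table at 2 h held 28 of 28 plastid ribosomal protein genes, all raised, and at 8 h it held 1, raised. Of 33 replication genes it held 32 lowered at 2 h and 7 lowered at 8 h. Photosynthesis genes were raised at 7 and lowered at 3 of 21 at 2 h, and raised at 18 and lowered at 1 at 8 h. Of 8 chloroplast chaperones 7 and 6 were raised at 2 and 8 h, and all 5 proteases were raised at both times. Chlorophyll synthesis genes were raised at 7 and 5 of 8, oxidative stress genes at 7 and 9 of 11 with 1 lowered each time, and storage genes at 6 and 7 of 10 with 3 lowered at 2 h. The 3 cytosolic ribosomal protein genes were lowered at 8 h. The remaining lists went as follows in the authors' deposited table: nitrogen genes raised at 6 of 7 at 2 h and at 3 with 1 lowered at 8 h, non-plastid chaperones raised at 2 and 4 of 5 with 1 lowered each time, autophagy genes raised at 2 and 3 of 3, and stress-induced light-harvesting relatives raised at 3 and 1 of 3. Every list member carries its name because the authors called it with rapamycin, so these counts are no independent evidence, and a gene missing from a table is not shown to be unchanged.

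The authors' deposited table held 1939 genes at 2 h (890 raised, 1049 lowered) and 1702 at 8 h (688 raised, 1014 lowered), all with a log2 size of at least 1 and adjusted p up to 0.0099 and 0.0097. Of 985 genes in both, 983 had the same direction.

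Genes changed by rapamycin at 8 h also differed between the strains at 48 h of vitamins. HSP22E, HSP22F, DEG1C, BCS1 and AIH2, raised in the authors' deposited table, rose more in DHC16 (AIH2 by log2 4.06 ± 0.65). FMG1-2, lowered there, fell in DHC16 (log2 -3.92, difference -3.72 ± 0.58). PHC22 and FAP212, also lowered there, rose at 48 h in both strains. Their rises were smaller in DHC16 (log2 4.37 and 3.38) than in A31 (8.73 and 8.08). PSBO, PSBP1 and LHCB5 went opposite ways, raised by rapamycin in the authors' deposited table (log2 1.59, 1.74 and 1.42) and lower in DHC16 at 48 h (-3.51, -3.46 and -3.55). THB1, with log2 4.21 in the authors' deposited table, had a strain difference of 0.20 (adjusted p = 0.92). Of the 673 raised genes tested, 232 had a higher change in DHC16 than in A31, where independent lists would share 62.3. Of the 994 lowered genes, 271 had a lower change in DHC16 than in A31, against 86.1. The other way, 41 raised genes had a lower change (58.3) and 16 lowered genes a higher one (92). In DHC16 itself 405 of these 994 fell at 48 h and 223 rose.

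Against the A31 change at 48 h, the comparison planned, the rapamycin changes correlated across 1667 genes with r = -0.087 (Spearman's rho 0.015, covariance -0.27). Of the genes that rose there, 201 were raised (independent lists 96.6) and 338 lowered by rapamycin (142.7), and of those that fell, 29 were raised (85.0) and 248 lowered (125.5). The lowered genes thus exceeded the number for independent lists in both directions. An excess over that number alone therefore shows no shared direction. With the 48 h against 12 h change of A31, r was 0.597, with the strain difference 0.546 (covariance 1.60), and with the DHC16 change 0.418. These are values over genes preselected by the authors for a large rapamycin change, and whether the rapamycin 0 h libraries are those of the count table is not given in the sources used here, so no value for shared controls could be simulated. Had the rapamycin change used the A31 0 h libraries, these would enter it and the strain difference with opposite signs. The DHC16 change holds none of them. The authors' 0 h levels had higher rank correlations with the 12 h libraries (0.704 to 0.757) than with the A31 0 h libraries (0.428 to 0.45). Any shared A31 12 h library would enter the 48 h against 12 h change with the same sign and raise the r of 0.597.

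**Figure D4:**
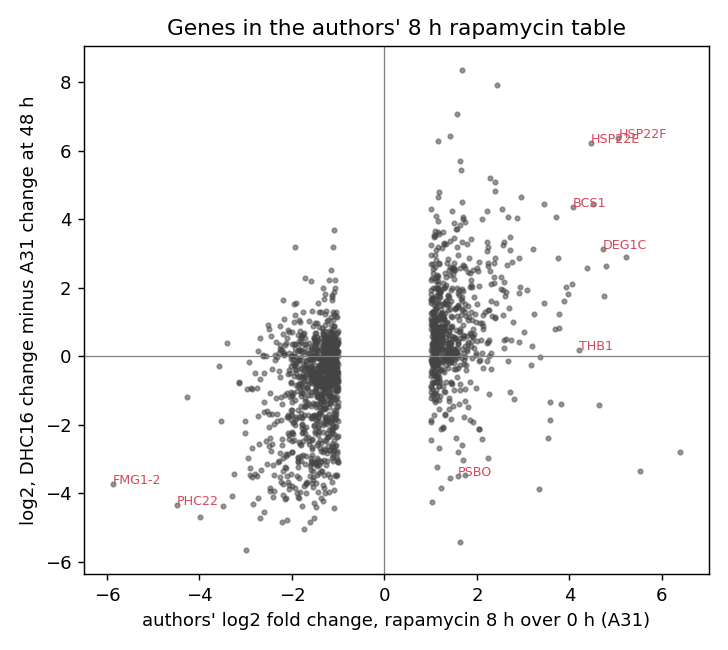
The authors' log2 fold change at 8 h of rapamycin over 0 h in A31 (horizontal) against the log2 strain difference of the 48 h vitamin change, DHC16 minus A31 (vertical), with 1 point per gene of the authors' 8 h table. HSP22E and HSP22F lie high in both (4.46 and 6.23, 5.06 and 6.39), FMG1-2 lies low in both (-5.88 and -3.72), and PSBO is opposite (1.59 and -3.51).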

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

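The tests of a label swap among the A31 libraries, of a culture without effective vitamins, of the scaling of genes lower in DHC16, of exchanged strains by the A31 libraries and of the genes called again without an A31 48 h library were chosen only after the result was seen, as was per-million scaling.

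The results here differed between the strains by a test of the difference itself, with 36 genes for the 12 h change and 2584 for the 48 h change. Log2 differences above 0 at 48 h, DHC16 minus A31, were 7.94 for SULTR2, 6.39 for HSP22F, 6.23 for HSP22E, 5.45 for RDP3, 5.28 for SLT2, 4.84 for AOT4, 4.65 for FXL7, 4.5 for PWR1, 4.35 for BCS1, 4.3 for PRX6 and 4.06 for AIH2. Smaller differences were 3.34 for SLT3, 3.14 for DEG1C, 2.72 for SBD1, 2.62 for APG8, 2.39 for HSP70B, 1.94 for GSTS1, 1.87 for FAP106, 1.85 for MCM5, 1.82 for PTB2, 1.69 for APG3, 1.67 for CLPB3 and FAP289, 1.64 for FAP63, 1.48 for CHLM, 1.35 for VIPP1, 1.31 for FAP210, 1.19 for TLP2, 1.09 for RPA30 and 1.07 for DEG1A. Of these TLP2 fell in both strains, less in DHC16 (-1.20 against -2.39), and PTB2, FAP289, FAP63, FAP210 and FAP106 fell in A31 and were not called in DHC16 (-0.47, -0.36, -0.30, -0.33 and 0.52). TLP2 stood at 709 to 742 normalized counts in A31 and 266 to 334 in DHC16 at 0 h, and at 120 to 157 and 75.7 to 177 at 48 h. FAP63, FAP289 and FAP210 were likewise higher in every A31 library at 0 h, and the strains overlapped at 48 h. For these genes the strains came together rather than apart. FAP106 and PTB2 were higher in every DHC16 library at 48 h. Without A31 48 h library 22 the differences of PTB2 (1.28, adjusted p = 0.057), FAP63 (0.91, 0.097), FAP210 (0.75, 0.12) and TLP2 (1.00, 0.056) were not called, nor without library 19 those of HSP70B (0.86, 0.12), VIPP1 (1.16, 0.077) and RPA30 (0.59, 0.11). For HSP70B and VIPP1 6 other libraries of A31 0 h and DHC16 did the same, for TLP2 and FAP210 5, for FAP63 3 and for RPA30 2, with adjusted p from 0.051 to 0.099.

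Photosynthesis genes were lower in DHC16 at 48 h, with differences of -4.26 for PSBX, -3.55 for LHCB5, -3.51 for PSBO, -3.47 for RBCS2A and -3.46 for PSBP1. Others were -5.42 for RBD2, -4.74 for GAS28, -4.69 for FAP212, -4.34 for NAB1, -3.84 for HCP3, -3.72 for FMG1-2, -3.16 for MME3, -2.76 for CYCA1, -2.74 for RPL37a, -2.6 for RPS25, -2.07 for ACS3, -1.66 for PRPL13, -1.59 for MAS1, -1.47 for PRPL33, -1.42 for GDH2, -0.91 for DVR1 and -0.8 for OHP1. Of these PRPL13, PRPL33, GDH2 and MAS1 were not called with per-million scaling, and RPL37a, RPS25, PRPL13, GDH2, MAS1 and OHP1 not with quantile scaling. DVR1 and OHP1 changed sign with per-million scaling (0.36 and 0.46), and were not called without A31 48 h library 22 (DVR1, -0.51, adjusted p = 0.11) or 19 (OHP1, -0.54, 0.086), nor without 6 and 5 others of A31 0 h and DHC16 (adjusted p 0.05 to 0.073). For PHC19 (-4.84), SMC2 (-4.41), PHC22 (-4.36), GOX8 (-4.17), ALK3 (-4.13), SRR1 (-4), FTSZ2 (-3.96), SULTR2 and PRX6 a 0 h level lay under 3 reads, so these values depend on the pseudocount and are no bound. The differences of PRX6 (adjusted p = 0.17) and SMC2 (0.052) were not called with edgeR, nor that of PRX6 (0.07) with DESeq2, and GOX8 was not called with edgeR (0.53), DESeq2 (0.06) or a pseudocount of 0.1 (0.11). RPA30 was not called with quantile scaling (0.097), nor HSP70B with edgeR (0.11) or DESeq2 (0.075). At 12 h the differences were -2.47 for FAP212, 1.63 for FAP289 and 1.25 for ACS3. Other splits of the libraries by strain within each time called at least as many genes as the real 36 in 2 of 100 splits, the real one included, with a highest other of 47. These splits mix the strains, which raised the median residual SD from 0.328 to at least 0.351, so they do not say whether chance can be excluded.

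The A31 libraries of 48 h differ, with library 19 near 0 h and library 22 near 12 h. A swap with a 0 h library would need a 0 h library nearer to library 22, and 0 of 6 were. A difference in depth is argued against, since after thinning library 19 stayed nearer to 0 h than to library 22 by a rank correlation of 0.089, and a DHC16 library by the 92.9% of 28 strain-separating genes at which library 19 lay nearer the A31 mean. A mixture of the 0 h state with library 22 itself would give the same share of library 22 from genes higher and lower in it. The shares were 21.2% (17.8 to 23.2%, 173 genes) and 55.9% (50.8 to 65.5%, 13 genes), which differ by 34.7 points. The genes were picked by their extreme values in library 22, and a partner unlike library 22 need not give equal shares. A mixture is therefore not excluded. RNA from a culture without effective vitamins, a wrong label included, stays a candidate explanation, as METE stood at 1001 in library 19, but this rests on a single gene. Library 19 was not at the 0 h state throughout, with CYCA1 at 176 (A31 0 h 7.73 to 15.3) and FAP212 at 2182 (5.34 to 13.4). No culture without vitamins was available at 48 h, so these rises cannot part the vitamins from time. A biological difference between the cultures stays open and untested.

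The genes that changed in DHC16 at 48 h and not likewise in A31 were weighed against 3 technical explanations. For the genes higher in DHC16 the lowest median difference under 3 other scalings was 1.55, so these scalings did not remove it. None of them moved the median of all genes down by much (1.28, 0.06 and -0.01, against 0.05 as deposited). The scaling factors as such are therefore not excluded. For the genes lower in DHC16 the median moved from -1.73 to -0.49 with per-million scaling, so the scaling stays open there as well. An exchange of strain labels among the 48 h libraries would need an A31 library out of place and is argued against, since the lower of the A31 libraries lay nearer A31 at 89.3% of 28 strain-separating genes (95% range 71.8 to 97.7%) and the other at 92.9%. In the DHC16 libraries 78.6, 71.4 and 67.9% lay nearer DHC16, short of the 90% set beforehand, a bound that changes of these genes at 48 h can break without an exchange. Whether a single discordant A31 library is the whole cause could not be decided by leaving it out. Of the 2584 genes, 82.5% were called again in the same direction without library 19 and 85% without library 22. These genes were selected by a test on both libraries, which favours genes at which the libraries agree. Leaving 1 library out also took their disagreement out of the shared spread. Being called again was therefore favoured from the start, and no conclusion is drawn from it. The bound set beforehand, 90% with a difference of at least 2-fold, could not be met, as 86.6% had it with both libraries, 79.9% without library 19 and 83.2% without library 22. How far a discordant library moves the size of single genes stays open. A biological difference between the strains may add to the pattern, and as the labels do not name the depleted strain it stays untested.

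The large change from 0 h to 12 h in A31 was 8634 genes. It was 8365 without the 50 most abundant genes and 8474 with every library thinned to 7458423 reads, so neither abundant genes nor depth account for it. Among 10 splits each, the real one was the 1 split with as many genes for the 12 h change in A31 (8634, highest other 0) and in DHC16 (8153, highest other 0), for the 48 h change in DHC16 (7933, highest other 0) and for the strains at 0 h (1353, highest other 1), and the splits are too few for a share under 0.05.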

How the results depend on the processing

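Per-million scaling, all tested genes as background, the list tests at 12 h, the DHC16 change beside rapamycin and the leave-outs of other groups' libraries were chosen only after the data were seen. Of the values of named genes, 4218 kept direction and side of the threshold, 287 kept direction and were not called, and METE for the 48 h strain difference became called without A31 48 h library 22. The cause was not tested unless stated.

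At least 2-fold, which asks for larger changes, the counts were 5564 and 2510 in A31 at 12 and 48 h, 5285 and 5110 in DHC16, and 714 at 0 h. With a stricter filter, which tests fewer genes, they were 5507 in A31 and 5185 in DHC16 at 12 h. With only the groups compared, which leaves fewer libraries for the spread, they were 297 in A31 at 48 h, and 502 and 1671 for the strain differences at 12 and 48 h. The strain difference at 12 h gave 335 with per-million scaling, 183 with DESeq2 and 11 with the replicate number as a block. At 48 h it gave 9587 with per-million scaling and 2123 with the block, and at 0 h 7444 with per-million scaling, 769 with quantile scaling and 1212 with the block. The numbers do not pair the strains throughout, as 4 of 8 pairs, all 3 of 0 h included, correlated above 0.1 and best with their own number (-0.084 to 0.222). With the block DVR1 (adjusted p = 0.12) and OHP1 (0.078) were not called for the 48 h strain difference.

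Leave-outs ranged from 953 (without A31 48 h library 22) to 7205 (without 19) for A31 at 48 h, from 3 (without DHC16 12 h library 16) to 426 (without A31 48 h library 19 or 22) for the strain difference at 12 h, from 1962 to 4188 (without A31 48 h library 22) at 48 h, and from 535 (without A31 0 h library 7) to 2568 (without A31 48 h library 19) at 0 h. A group left with 1 library is assumed to vary like the others.

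Directions reversed with per-million scaling for PSBO (0.148), CGE1a (0.112) and OHP1 (0.276) in DHC16 at 12 h, OHP1 (0.174) in DHC16 at 48 h, and METE (0.33), CGE1a (1.062), OHP1 (0.464) and DVR1 (0.356) for the 48 h strain difference. They reversed with quantile scaling for RBCS2A (0.385) and RPL37a (0.071) in DHC16 at 12 h and CGE1a (0.15) for the 48 h strain difference, where CGE1a (not called) ran over the leave-outs from -0.484 to 0.154, the latter without DHC16 0 h library 1.

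Of 10 lists, camera at the preset correlation called 4 for the 48 h strain difference, an estimated correlation 0, fry 6, fry with mixed directions 7, and all genes as background 5. In that order these were 1, 0, 7, 4 and 4 for A31 at 48 h, 6, 0, 10, 9 and 6 for DHC16 at 48 h, 2, 0, 7, 8 and 3 for A31 at 12 h, 2, 0, 8, 8 and 2 for DHC16 at 12 h, and 2, 0, 0, 0 and 1 for the strain difference at 12 h. The correlation with rapamycin was -0.087 as planned, 0.597 with the 48 h against 12 h change, 0.546 with the strain difference and 0.418 with the DHC16 change. The alternatives of the rapamycin comparisons were not run.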

Other observations

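The tests of the 3 gene groups below and the correlation with the rapamycin 0 h levels were chosen only after the result was seen.

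Flagellar genes moved with rapamycin and with time. Of 144 flagellar and ciliary genes in the authors' deposited table at 8 h, 140 were lowered and 4 raised, among them FMG1-2 (log2 -5.88) and FAP12 (-4.27), and the other named genes there had 163 lowered and 236 raised (Fisher p = 5.3e-38, adjusted 1.1e-36). The group was chosen after this result was seen, and the test counts genes as independent replicates. Its p-value is therefore no evidence about rapamycin, and the counts are a description. In the vitamin libraries 92 of 151 fell and 5 rose in A31 at 48 h (median -0.89), and 81 fell and 5 rose in DHC16 (median -0.66, which turned to 0.38 with per-million scaling). At 12 h 80 fell and 13 rose in A31, and 4 fell and 32 rose in DHC16. The strain difference at 12 h had a median of 0.85, with 3 genes called higher and 1 lower (camera adjusted p = 3.8e-22, adjusted p = 0.23 with an estimated correlation, fry 0.057). Before the vitamins, at 0 h, 3 of the 151 genes were higher and 16 lower in DHC16 (median -0.28, or -1 with per-million scaling). Part of the 12 h strain difference may therefore lie in the 0 h levels. At 48 h 6 were higher and 7 lower (Fisher p = 0.78).

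Sulfate transport and use genes were higher in DHC16 at 48 h at 4 of 7 and lower at 1, SULTR3 (-1.43), with a median of 2.72. Fry gave adjusted p = 1.4e-08 and camera 0.0055, with adjusted p = 0.079 with an estimated correlation, and Fisher's test p = 0.17. Pherophorins and gametolysins, proteins that build or degrade the cell wall, mostly rose at 48 h. Of 12 genes 10 rose in A31, and 8 rose and 1 fell in DHC16. The change was lower in DHC16 at 7 of 12 with none higher (median -2.37, or -1.33 with per-million scaling). Fry gave adjusted p = 5.2e-05, camera 6e-04 (0.16 with an estimated correlation) and Fisher's test adjusted 0.049. The Fisher's tests formed a family of 21 over 3 groups, and each set method a family of 21 as well, all on names from the authors' rapamycin tables.

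Genes of the authors' 8 h table were compared with the strain difference at 48 h as a hypothesis of a shared response. The 673 raised genes had a median of 0.72, where 10000 random lists of like expression gave -0.1 to 0.03, and the 994 lowered genes had -0.66, where random lists gave -0.03 to 0.09. A shared response may underlie this, but the overlap was not particular to the strain difference. In A31 at 48 h the raised genes had a median of 0.47, above random lists (-0.01 to 0.11). The lowered genes had 0.05 there, within random lists (-0.01 to 0.09). The 48 h against 12 h change of A31 correlated with the rapamycin change at r = 0.597. If the rapamycin change used the A31 0 h libraries, these would enter it with a minus and the strain difference with a plus. Such sharing would lower the correlation of 0.546, and the DHC16 change, with 0.418, holds none of these libraries. The authors' 0 h levels had rank correlations of 0.704 to 0.757 with the 12 h libraries over 2638 genes and 0.428 to 0.45 with the A31 0 h libraries, so the rapamycin 0 h values may come from other libraries than those of the count table.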
